A study of Mus musculus with 16 samples.

How the data were processed

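Gene expression was measured by bulk RNA sequencing of bone marrow-derived macrophages from C57BL/6J mice, which are macrophages grown from marrow cells with M-CSF, the growth factor that drives macrophage development. Per the labels' protocols, the marrow was cultured for 7 days with medium conditioned by L929 cells as the M-CSF source. Then 400000 macrophages were plated and starved for 4 hours in 0.5% serum. The 4 treatments, each of 4 hours, were PBS as the vehicle, thrombin, platelets at rest, and platelets activated by thrombin, with platelets taken from mouse blood. The thrombin dose is uncertain: the protocol states 0.01 U/mL, whereas the sample labels of the thrombin group state 0.1 U/mL. The labels of the activated platelet group state no dose. The interaction and the comparison of activated platelets with thrombin assume the same dose in both groups. Poly(A) libraries were made with a strand-preserving kit. There were 4 groups of 4 libraries, 16 in all, and each library was placed in its group by its title.

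The table held estimated counts per gene, deposited by the authors with no normalization. It named 46320 genes by symbol and NCBI gene identifier with RefSeq coordinates on GRCm39. Per the submitters' processing notes, cutadapt 2.5, STAR 2.7.2b and featureCounts 1.6.4 of the Subread package were used, and both GRCm39 and mm10 were named as genome builds. The notes give no role or order for these tools. The settings for strand and for reads that fit several places are not given in the sources used here. Antisense partners, overlapping genes and near-identical copies, such as the haemoglobin genes Hba-a1 and Hba-a2, are therefore uncertain as single genes. Of the values above 0, 25.5% were not whole numbers, although whole counts had been assumed when the design was fixed. All values were rounded to whole numbers, which changed 0.0073% of all counts. No column belonged to a sample outside the series. The 13 protein genes of the mitochondrial genome were not among the genes used here, so 28 of the 29 gene lists were tested.

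Counts were filtered with filterByExpr by group, leaving 15610 genes, and scaled by TMM. The main test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted on all 16 libraries as 4 groups with no block. P-values were two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. A gene is said to rise, fall or change only where it passed that threshold. There were 6 comparisons, among them the interaction, which is the thrombin effect with platelets minus the thrombin effect without them. Standard errors of log2 fold changes were taken from the F statistic. CPM values used TMM-scaled library sizes, M stands for mega, and CPM are given as mean ± SD of 4 libraries. The principal components used log2 CPM with a prior count of 2 over the 1000 most variable genes. Folds against a group with no counts were set against 3 counts over its 4 libraries, and with 1 to 3 counts the ratio carries an exact binomial 95% interval. Such intervals and floors cover counting error only.

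The gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone. Named by the rule were the 8 largest rises and 8 largest falls per comparison among called genes with at least 5 CPM in the higher group, no overlap of libraries and a symbol that is not a predicted model. The interaction used the call and the CPM rule alone. The rule added up to 2 rising and 2 falling members of each list with the smallest p, and 15 genes fixed in advance whatever their values. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen. Shares of counts in marker lists of other cell types were compared with an exact two-sided permutation test over the 70 arrangements of 4 against 4, whose smallest p is 0.0286.

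Groups shared replicate numbers, so it was checked whether the numbers pair libraries. After group means were removed, the 24 same-number correlations lay between 0.29 and 0.617, the other pairs lay between -0.436 and 0.253, and 16 of 16 libraries correlated best with their own number. The numbers were therefore taken to pair the libraries. This pairing comes from the data, since the labels do not say what a number marks. Nothing in the labels says that replicates came from separate animals or cultures. Ddx3y and Xist differ between replicate 1 and replicates 2 to 4, so these came from different animals, but replicates 2 to 4 may share a source. P-values measure the spread between these samples, which may be partly technical. The 24 within-group pairs differed by 8.65 to 36.8 times their counting noise (chi-square per degree of freedom over genes with at least 20 counts), so no library was a copy of another.

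Totals lay between 22.6 and 30.6 M counts. On simulated counts for resting platelets against vehicle (15488 genes), edgeR recovered 74.6%, 82.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 0 false calls among 171. With the replicate number as a block it recovered 92.5%, 97% and 100%, with 12 false calls among 205. The shares were 77.6%, 82.1% and 98.5% for limma-voom and 85.1%, 86.6% and 100% for DESeq2, with 0 false calls among 172 and 1 among 182. The changed genes had a mean of at least 1 CPM, and no trend with transcript GC content was simulated between groups. These shares and false calls may therefore not hold for the real libraries. Alternatives were the replicate block, DESeq2 1.42.0, limma-voom, RLE and upper quartile factors, no filter, a filter of 1 CPM in 4 libraries, a fit of the 2 compared groups alone, a 2-fold minimum, fry, and the omission of each library. A replicate block with a correction of each library for transcript GC content, the omission of each replicate number and fits without the platelet lists were added after the data were seen. GC content came from GENCODE vM21 transcripts of GRCm38, matched by gene name for 93.4% of tested genes, and no coordinates were taken from that build. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.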

Results

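Macrophages were exposed for 4 hours to vehicle, thrombin, resting platelets or thrombin-activated platelets, with 4 libraries per group. Thrombin is the protease that ends the coagulation cascade and activates platelets, the cell fragments that form clots and release stored proteins. The design asks what platelets do to macrophage transcripts, what thrombin does alone, and whether platelets act differently once thrombin has activated them. Totals were 22.6 to 27.7 M counts in vehicle libraries, 23.1 to 26.7 M counts with thrombin, 24.9 to 26.4 M counts with resting platelets and 28.0 to 30.6 M counts with thrombin-activated platelets. The 10 most abundant genes took 8.41% to 10.3% of each library. Macrophage transcripts were abundant in every group, for example Lpl, which encodes lipoprotein lipase, at 2870 ± 926 CPM (SD, n = 4) in vehicle.

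The first principal component held 44.4% of the variance and set the platelet groups apart from each other and from the groups without platelets, which overlapped. Vehicle libraries scored between -17.7 and -14.1, thrombin libraries between -16.7 and -10.9, resting platelet libraries between -0.8 and 2.5, and activated platelet libraries between 28.3 and 28.9. The second component, with 21.9%, set apart the replicate 1 libraries, which scored between 20 and 21.2 against 1 or lower for the others. Replicate 1 libraries also carried Ddx3y, a gene of the Y chromosome, at 85.1 to 93.2 CPM and Xist, the transcript of the inactive X chromosome, at up to 1.06 CPM. In replicates 2 to 4, Ddx3y stood at up to 0.27 CPM and Xist at 1060 to 1290 CPM. Replicate 1 thus has the transcripts of male cells and replicates 2 to 4 those of female cells, in all 4 groups.

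**Figure D1:**
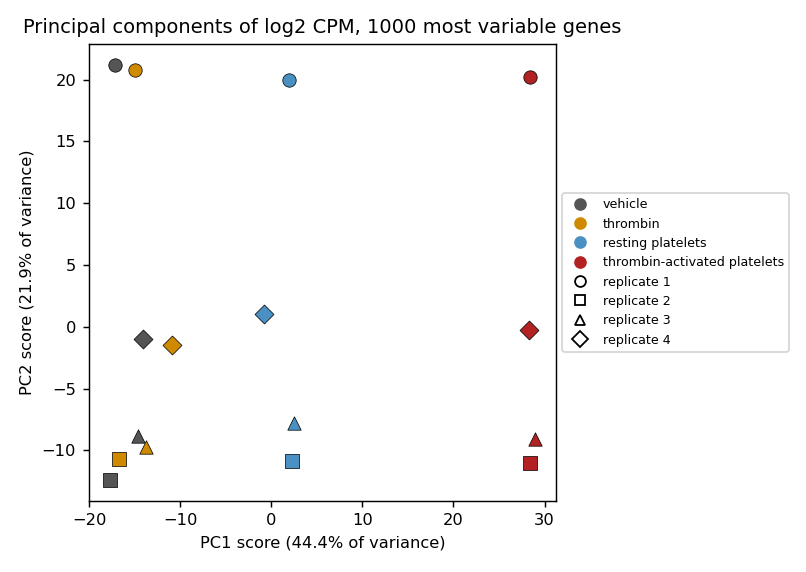
Scores of the 16 libraries on the first and second principal components of log2 CPM over 1000 genes, coloured by group and shaped by replicate number. The platelet groups part from the others along the first component (44.4% of variance), where vehicle and thrombin overlap, and replicate 1 stands above the others on the second (21.9%).

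Transcripts of other cell types were followed through fixed marker lists, since platelets bring RNA of their own. Platelet and megakaryocyte markers made up 0.0229% ± 0.00227 of counts in vehicle, 0.0231% ± 0.00134 with thrombin, 0.0264% ± 0.00222 with resting platelets and 0.0464% ± 0.00257 with activated platelets (SD, n = 4). The activated platelet group was higher than each other group (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.125 over 35 tests; all 4 libraries higher). That p is the smallest this design allows, and 8 of the 35 tests reached it. The resting platelet group did not pass against vehicle in this test, which leaves out the pairing by replicate number (exact p = 0.0857). Its share was higher within each number, at 0.0288%, 0.0243%, 0.0277% and 0.0247% against 0.026%, 0.0205%, 0.0222% and 0.023% for replicates 1 to 4. That paired difference was not tested. Pf4, a platelet chemokine present at 199 ± 19.3 CPM in vehicle macrophages, makes up most of the list. Without it the shares were 0.003%, 0.00308%, 0.00576% and 0.0214% in the same order, and resting platelets then differed from vehicle (exact p = 0.0286).

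Erythroid markers took 0.000983% ± 9.2e-05 of counts in vehicle and 0.00218% ± 0.000203 with activated platelets, a difference with exact permutation p = 0.0286 (adjusted p = 0.125, n = 4). Lymphocyte markers went the other way, from 0.00274% ± 0.000659 to 0.00103% ± 0.000243 (exact p = 0.0286, adjusted p = 0.125), led by Ighm, the heavy chain of immunoglobulin M. Neutrophil markers (0.00762% in vehicle and 0.0107% with activated platelets, exact p = 0.2), dendritic cell markers (0.0241% and 0.0195%, p = 0.114) and mast cell and basophil markers (0.000207% and 0.000189%, p = 0.657) did not pass this exact permutation test, which leaves out the pairing by replicate number. Stromal cell markers such as the collagen gene Col1a1 were more abundant, at 0.434% ± 0.15 in vehicle and 0.38% ± 0.141 with activated platelets, with exact p = 0.571. Within replicate numbers, the shares of stromal and of dendritic cell markers were lower with activated platelets in 4 of 4 and that of mast cell and basophil markers in 3 of 4, while that of neutrophil markers was higher in 3 of 4. These paired differences were not tested.

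Thrombin alone changed few genes, and the largest changes were in genes that handle zinc. Slc39a10, a zinc importer (chromosome 1, 46846704 to 46964952, GRCm39), rose from 60.1 ± 4.75 to 191 ± 12.3 CPM, a log2 fold change of 1.67 ± 0.08 (SE; adjusted p = 5.66e-09). The metallothioneins, which bind zinc, fell. Mt2 (chromosome 8, 94899246 to 94900195) dropped from 6.9 ± 1.16 to 0.98 ± 0.384 CPM, 6.97-fold lower (adjusted p = 8.39e-06). Mt1, 2.51-fold lower, went from 42.8 ± 3.63 to 17.1 ± 1.55 CPM (adjusted p = 4.56e-07). The zinc exporter gene Slc30a1, chosen after these values were seen, stood at a log2 fold change of -0.61 ± 0.15 and did not pass (adjusted p = 0.122; 2.31e-07 with replicate as a block). Smaller changes included the transcription factor gene Zfp143, which rose 1.53-fold (adjusted p = 0.000419), and Klhl17, 1.42-fold lower (adjusted p = 0.00312).

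In all, edgeR called 45 of 15610 genes for thrombin against vehicle, 14 higher and 31 lower, and 1786 genes had an unadjusted p under 0.05. With replicate as a block the call numbers were 1285, 610 higher and 675 lower, including all 45. Across genes, these log2 fold changes went with transcript GC content (Spearman rho = -0.443; genes are not independent replicates). Omitting a single library left 8, 10, 27 and 11 calls for vehicle 1 to 4, and 7, 12, 21 and 10 for thrombin 1 to 4. Without a whole replicate number there were 4, 6, 9 and 6.

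Few members of the fixed lists responded to thrombin. Of the 17 macrophage identity genes only Cd14, the lipopolysaccharide co-receptor, was called, with a log2 fold change of -0.29 ± 0.06 (adjusted p = 0.0447; 1 member adjusted over the list alone). With the block 5 of those members were lower, and camera then gave p = 0.0447 for the list against 0.293 without the block (adjusted p = 0.712 with the block and an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose by 0.39 ± 0.07 in log2 among 13 anti-inflammatory feedback genes (adjusted p = 0.0422), and the chemokine receptor gene Ccr1 rose by 0.43 ± 0.08 among 17 receptors for platelet products (adjusted p = 0.0404). Each was also the 1 member called when adjusted over the list alone. With the block, adjusted p was 0.000208 for Cd14, 0.000531 for Il1rn and 0.000523 for Ccr1. With GC correction as well it was 0.00433, 0.0138 and 0.0185. Without the block these calls lay near the threshold, and most fits with 1 library fewer lost them. Omitting any 1 of the 8 libraries ended those of Cd14 (adjusted p = 0.0717 to 0.162) and Ccr1 (0.0508 to 0.145). That of Il1rn ended (0.0724 to 0.145) without any library except thrombin 3. A fit of these 2 groups alone gave adjusted p = 0.22 for Cd14 and 0.199 for Il1rn, and limma-voom gave 0.0502 for Il1rn.

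Interferon-stimulated genes as a list lay lower with thrombin (camera, adjusted p = 0.014), but adjusted p = 0.963 with an estimated correlation. In edgeR 0 of its 21 members were called, with 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, and 1 lower with the block. In no other list did camera pass (adjusted p of 0.293 or higher). The inflammatory genes Il1b (log2 fold change -0.51, adjusted p = 0.587) and Tnf (-0.36, adjusted p = 0.618) did not pass.

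**Figure D2:**
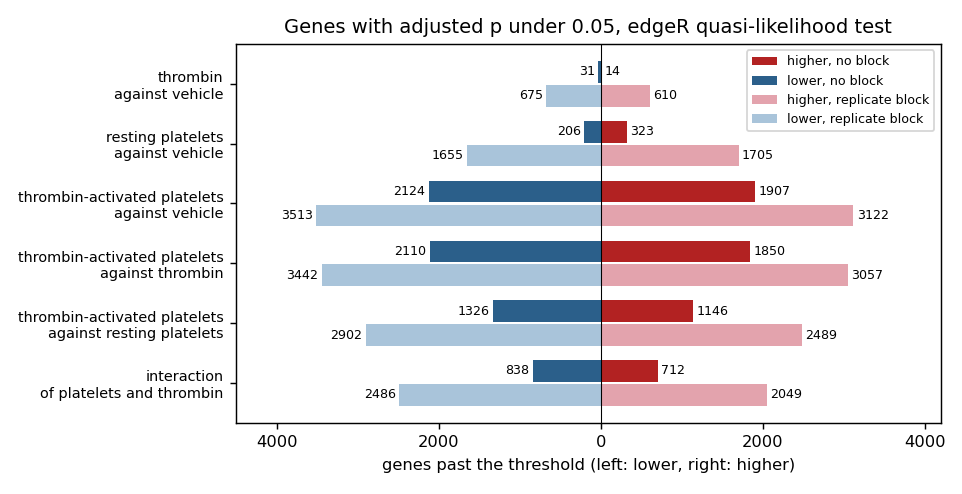
Genes past the adjusted threshold in each comparison by edgeR, lower to the left and higher to the right, without and with replicate number as a block. Thrombin against vehicle has 45 calls without the block and 1285 with it, and thrombin-activated platelets against vehicle 4031 and 6635.

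Resting platelets changed more genes than thrombin did in number of calls, most by less than 2-fold, and the largest rises were in platelet and haemoglobin transcripts. Outside those, Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (chromosome 1, 149975782 to 149983985), rose from 15.7 ± 1.14 to 49.9 ± 13.8 CPM, 3.17-fold (adjusted p = 0.000868). Gjb2, a gap junction protein, rose 3.99-fold (adjusted p = 0.00162), Has2, a hyaluronan synthase, 2.97-fold (adjusted p = 0.00329) and Htr1b, a serotonin receptor, 2.8-fold (adjusted p = 0.00807). Among the falls, Map2k6, a kinase upstream of p38, was 2.5-fold lower, from 8.08 ± 1.03 to 3.24 ± 0.584 CPM (adjusted p = 5.46e-05). The interferon-inducible gene Gbp9 was 1.54-fold lower (adjusted p = 0.000323).

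Platelet transcripts appeared in the same libraries. Of the 21 platelet and megakaryocyte markers tested, 11 rose and 0 fell (14 adjusted over the list alone; camera, adjusted p = 2.58e-24, adjusted p = 0.0217 with an estimated correlation and 0.0582 with that and the block). Ppbp, a platelet chemokine, went from 0.242 ± 0.143 to 4.68 ± 3.27 CPM, 18.7-fold (adjusted p = 0.00123; 0.0512 by limma-voom). Gng11 rose 1.8-fold (adjusted p = 0.00588). Gp9, a subunit of the platelet von Willebrand factor receptor, had 109 counts against 0 in vehicle, at least 37.6-fold higher against a floor of 3 counts over the group. Nrgn had 642 counts against 2, a ratio of 332 (95% counting interval 91.6 to 2750). The haemoglobin gene Hba-a1 had 115 counts against 1, a ratio of 119 (20.9 to 4740). Pf4 stood at 207 ± 11.1 CPM against 199 ± 19.3 and was not called (adjusted p = 0.701).

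Among 16 TGF-beta and BMP response genes 7 rose, among them Tgfbr1, Ski, Skil and Smad7, and 0 fell (8 higher adjusted over the list alone, 1 lower at an unadjusted p under 0.05, and 10 higher and 1 lower with the block). Tgfbr1, a TGF-beta receptor, rose 1.51-fold (adjusted p = 0.00123) and Ski, a repressor of the pathway, 1.24-fold (adjusted p = 0.00137). Camera gave adjusted p = 2.8e-07 for the list, and adjusted p = 0.0978 with an estimated correlation (0.0111 with the block). Of the 22 immediate early genes Fos rose 1.7-fold (adjusted p = 0.000949) and Nr4a1 1.71-fold (adjusted p = 0.0271), with 9 higher and 1 lower adjusted over the list alone and 11 higher and 3 lower with the block. The list passed camera (adjusted p = 2.38e-05), with adjusted p = 0.141 with an estimated correlation. The call of Nr4a1 ended without vehicle 1 (adjusted p = 0.064), 2 (0.0621) or 4 (0.0746), without resting platelets 1 (0.0612), 2 (0.0659) or 4 (0.0748), and by limma-voom (0.067).

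Inflammatory genes moved both ways. Of 19 cytokine and NF-kB target genes, Ptgs2 rose and Ccl4, a chemokine, was 1.55-fold lower (adjusted p = 0.0192), which were also the calls adjusted over the list alone, against 4 higher and 2 lower with the block. The call of Ccl4 ended without vehicle 1 (adjusted p = 0.0614) or 2 (0.0621) and without resting platelets 1 (0.0749) or 2 (0.0648). Il1b, at 4.3 ± 1.05 against 2.45 ± 1.14 CPM, did not pass (adjusted p = 0.128; 0.00442 with the block). Camera gave adjusted p = 0.0231 for this list and adjusted p = 0.514 with an estimated correlation. Of 19 glycolysis and hypoxia genes Vegfa, a growth factor for blood vessels, rose 1.95-fold (adjusted p = 0.000949) and Hk2, a hexokinase, 1.32-fold (adjusted p = 0.0127), in a list with 3 higher and 1 lower (4 and 1 adjusted over the list alone, 6 and 2 with the block; camera, adjusted p = 0.102). Of the 17 receptors for platelet products 3 rose, Tgfbr1 and Ccr1 among them (6 higher and 1 lower adjusted over the list alone, 9 and 4 with the block), with adjusted p = 0.0095 by camera and adjusted p = 0.509 with an estimated correlation (0.0111 with the block). Il1rn rose 1.36-fold (adjusted p = 0.00453), and Tgm2, a transglutaminase, 2.02-fold (adjusted p = 0.0102).

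Among 17 macrophage identity genes Cx3cr1, the fractalkine receptor, rose 1.91-fold with resting platelets (adjusted p = 0.0111; 0.0511 with no filter on low counts) and Cd14 1.2-fold (adjusted p = 0.025), with 3 rises adjusted over the list alone, 6 rises and 2 falls with the block, and camera at adjusted p = 0.364. The call of Cd14 ended without vehicle 1 (adjusted p = 0.0769), 2 (0.0854) or 4 (0.053), without resting platelets 2 (0.0691) or 4 (0.0706), and in a fit of the 2 groups alone (0.0813). The sterol list of 20 genes passed camera (adjusted p = 0.00738, adjusted p = 0.514 with an estimated correlation) while edgeR called 0 members, with 6 higher and 2 lower at an unadjusted p under 0.05, 5 and 2 adjusted over the list alone, and 10 and 2 with the block. Interferon-stimulated genes lay lower (camera, adjusted p = 0.0194, 0.0501 with the block, and adjusted p = 0.719 with an estimated correlation), with 0 of 21 called by edgeR, 3 lower at an unadjusted p under 0.05 and 1 lower with the block. Heat shock genes passed camera (adjusted p = 0.0231, adjusted p = 0.472 with an estimated correlation) with Hsph1 1.29-fold higher (adjusted p = 0.00728) as the 1 call of 10 and 5 higher with the block. The 11 cAMP response genes (camera, adjusted p = 0.0194, adjusted p = 0.141 with an estimated correlation) held 1 rise, 3 rises and 1 fall adjusted over the list alone, and 6 and 1 with the block. The 16 coagulation genes (camera, adjusted p = 0.0211, adjusted p = 0.141 with an estimated correlation) held 1 rise, and 4 with the block.

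In all, edgeR called 529 genes for resting platelets against vehicle, 323 higher and 206 lower, of which 36 and 3 changed at least 2-fold. Log2 fold changes went with transcript GC content here too (Spearman rho = -0.34). With the block there were 3360, 1705 higher and 1655 lower. The count fell to 235, 221 and 275 without vehicle 1, 2 and 4, and to 208, 230 and 273 without resting platelets 1, 2 and 4. Without replicate number 1, 2 or 4 there were 58, 144 and 116 calls.

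Thrombin-activated platelets changed many genes against vehicle, and the largest rises were in platelet and haemoglobin transcripts. Outside those, Trem1, a receptor that amplifies inflammatory signals (chromosome 17, 48539763 to 48553955), rose 22.3-fold from 0.346 ± 0.133 to 7.89 ± 1.93 CPM (adjusted p = 3.35e-08). Il1b, which encodes interleukin-1 beta (chromosome 2, 129206490 to 129213059), rose 7.27-fold to 17.8 ± 3.11 CPM (adjusted p = 1.65e-06). Ptgs2 rose 9.42-fold to 148 ± 44.8 CPM (adjusted p = 5.13e-08), Tgm2 10.1-fold to 633 ± 127 CPM (adjusted p = 1.33e-08) and Vegfa 7.22-fold to 285 ± 48.4 CPM (adjusted p = 1.05e-09). Cd14 rose 3.28-fold from 214 ± 18.9 to 701 ± 10.7 CPM (adjusted p = 2.9e-11). The potassium channel gene Kcnj2 was 8.44-fold lower, from 69.9 ± 22.7 to 8.27 ± 1.9 CPM (adjusted p = 7.97e-07), and Ptx3, a soluble pattern receptor, 7.91-fold lower (adjusted p = 3.38e-05). The zinc genes followed the thrombin comparison, with Slc39a10 2.82-fold higher (adjusted p = 1.73e-09) and Mt2 7.45-fold lower (adjusted p = 1.26e-07).

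Platelet markers were the most uniform group, with 19 of 21 higher and 0 lower (21 higher adjusted over the list alone and with the block; camera, adjusted p = 1.68e-38, adjusted p = 0.00188 with an estimated correlation). Ppbp reached 35.7 ± 7.46 CPM and Gng11 40.9 ± 5.24 CPM, and Gp9 had 921 counts against 0, at least 277-fold higher against the same floor. Pf4 rose 1.25-fold (adjusted p = 0.00219). Hba-a1 had 704 counts against 1, a ratio of 635 (95% counting interval 114 to 25100). The gene groups that follow were measured in libraries with this platelet share. Erythroid markers gave 2 rises among 3, Hba-a1 and Hba-a2 (2 adjusted over the list alone; camera, adjusted p = 3.52e-06, adjusted p = 0.0135 with an estimated correlation).

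Of 11 cAMP response genes 10 rose and 1 fell (the same numbers adjusted over the list alone and with the block). The phosphodiesterase gene Pde4d (chromosome 13, 108790711 to 110092503) rose 3.48-fold from 4.26 ± 0.514 to 14.9 ± 2.37 CPM (adjusted p = 3.33e-08), and the cAMP-inducible repressor gene Crem 2.26-fold (adjusted p = 6.01e-07). Il10, an anti-inflammatory cytokine, was 3.21-fold lower at 0.151 ± 0.106 CPM (adjusted p = 0.00279). The list passed camera (adjusted p = 6.21e-10, adjusted p = 0.00188 with an estimated correlation). Of 16 TGF-beta and BMP response genes 10 rose and 0 fell (11 higher adjusted over the list alone, 11 higher and 2 lower with the block; camera, adjusted p = 5.08e-11, adjusted p = 0.0181 with an estimated correlation). Tgfbi rose 2.64-fold (adjusted p = 1.5e-08) and Ski 1.72-fold (adjusted p = 6.14e-09).

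Of 22 immediate early genes 12 rose and 3 fell (13 and 4 adjusted over the list alone; camera, adjusted p = 5.32e-06, adjusted p = 0.0659 with an estimated correlation). Fos rose 4.19-fold (adjusted p = 2.04e-09) and Nr4a2 2.56-fold (adjusted p = 4.79e-07), whereas Klf2, a factor that restrains inflammation, was 1.99-fold lower (adjusted p = 0.000314). Of 19 inflammatory genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with no call by camera (adjusted p = 0.0816; 0.0487 with the block, and 0.544 with the block and an estimated correlation). Beside Il1b and Ptgs2, Cxcl2 rose 2.08-fold (adjusted p = 0.00268), and the chemokine genes Ccl4 and Ccl3 were 4.06-fold (adjusted p = 5.23e-08) and 3.3-fold lower (adjusted p = 2.42e-05). Tnf, at 13.2 ± 6.06 against 14.3 ± 2.56 CPM, did not pass (adjusted p = 0.772), but did without activated platelets 2 (adjusted p = 0.0373), whose 22.2 CPM lay above 9.36 to 10.7 in the other libraries of its group. Ccl2 did not pass (adjusted p = 0.754). Il6 had 0 to 3 counts per vehicle library and 5 to 9 per activated platelet library, too few to be tested.

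Anti-inflammatory feedback genes lay higher as a list, with 6 of 13 higher and 2 lower (the same adjusted over the list alone; camera, adjusted p = 0.00512, adjusted p = 0.0352 with an estimated correlation). Il10 was among the falls, 3.21-fold lower (adjusted p = 0.00279 by edgeR). Il1rn rose 2.39-fold (adjusted p = 6.97e-09) and Socs3 1.63-fold (adjusted p = 0.00122). Of 16 coagulation and fibrinolysis genes 6 rose and 0 fell (the same adjusted over the list alone, and 7 higher and 3 lower with the block; camera, adjusted p = 0.00512, adjusted p = 0.0614 with an estimated correlation). They included F5, coagulation factor V, 4.99-fold higher (adjusted p = 1.8e-07), and F3, tissue factor, 2.74-fold higher (adjusted p = 0.0011). Of the 9 genes of IL-4 type alternative activation tested, 4 rose and 3 fell (the same adjusted over the list alone and with the block), Arg1 6.44-fold up to 1 ± 0.217 CPM (adjusted p = 0.000143) and Clec10a 2.85-fold down (adjusted p = 0.00159). Camera gave adjusted p = 0.0288 for that list, 0.143 with the block and adjusted p = 0.268 with an estimated correlation. The macrophage identity list held 4 rises and 2 falls among 17 (the same adjusted over the list alone; 8 and 7 with the block; camera, adjusted p = 0.0107, 0.0701 with the block, and adjusted p = 0.398 with an estimated correlation), with Cd14 among the rises and Maf 1.63-fold lower (adjusted p = 0.00164).

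Of the 17 receptors for platelet products 6 rose and 3 fell (7 and 3 adjusted over the list alone, 8 and 5 with the block; camera, adjusted p = 0.00512, adjusted p = 0.398 with an estimated correlation, 0.0181 with that and the block). The C-type lectin receptor gene Clec4e rose 2.82-fold (adjusted p = 1.92e-08) and Ccr1 2.32-fold (adjusted p = 2.11e-08), while Tgfbr2 was 1.36-fold lower (adjusted p = 0.000307). Phagocytosis genes gave 1 rise and 5 falls among 17 (2 and 5 adjusted over the list alone, 3 and 8 with the block; camera, adjusted p = 0.266), with Gas6 1.75-fold lower (adjusted p = 4.28e-05). Of 14 lipid-associated macrophage genes Lpl was 2.19-fold lower (adjusted p = 0.00298) and the fatty acid carrier gene Fabp4 2.08-fold lower (adjusted p = 0.0102), with 1 rise and 6 falls under the block (camera, adjusted p = 0.354, 0.01 with the block, and 0.452 with the block and an estimated correlation). Of 13 LXR targets the cholesterol exporter gene Abca1 rose 2.24-fold (adjusted p = 3.33e-06), in a list with 2 rises, 5 rises and 1 fall with the block, and camera at adjusted p = 0.138 (0.0461 with the block, and 0.226 with the block and an estimated correlation). Glycolysis and hypoxia genes went both ways, with 4 rises and 5 falls among 19 (6 and 6 adjusted over the list alone, 7 and 8 with the block; camera, adjusted p = 0.673). Pfkfb3 rose 1.76-fold (adjusted p = 5.74e-07), and Pdk1, a kinase that restrains pyruvate oxidation, was 2.02-fold lower (adjusted p = 1.45e-09).

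Thrombin receptor genes showed 2 rises among 4 tested (Gp1ba and F2rl2, both also on the platelet list; 2 adjusted over the list alone; camera, adjusted p = 0.00786, adjusted p = 0.0457 with an estimated correlation, 0.0984 with the block). F2r, the main thrombin receptor, stood at 4.44 ± 1.07 against 3.75 ± 0.762 CPM and was not called. F2rl1 and F2rl3 had too few counts to be tested. In all, edgeR called 4031 genes for thrombin-activated platelets against vehicle, 1907 higher and 2124 lower, of which 332 and 266 changed at least 2-fold. With the block there were 6635, 3122 higher and 3513 lower, and without replicate number 1 there were 2522.

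**Figure D3:**
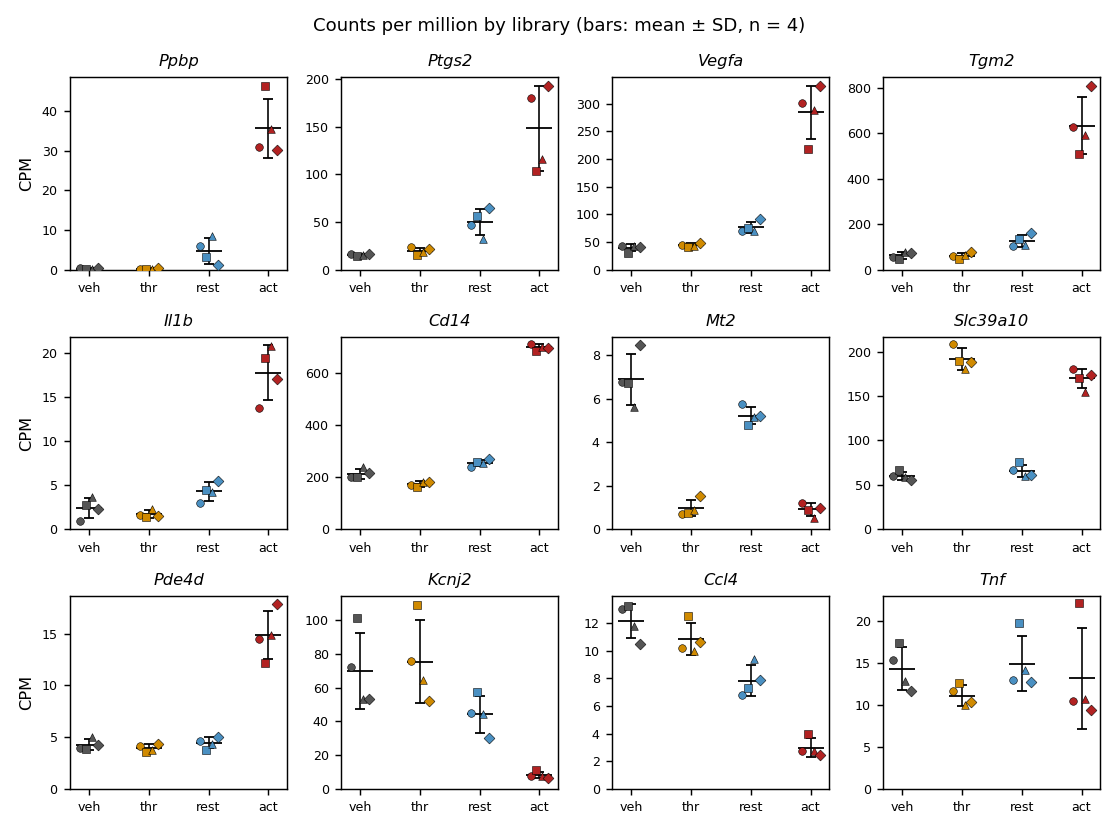
CPM per library of 12 genes by group (veh, vehicle; thr, thrombin; rest, resting platelets; act, thrombin-activated platelets), with bars for the mean and SD of 4 libraries. Cd14 reaches 701 ± 10.7 CPM with activated platelets, whereas Mt2 lies near 1 CPM in both groups that received thrombin.

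Activated platelets were also compared with thrombin alone, which gives the effect of platelets when thrombin is present. Il1b rose 10.4-fold from 1.72 ± 0.416 CPM (adjusted p = 4.3e-07), Trem1 18.2-fold (adjusted p = 5.67e-08), Tgm2 10.2-fold (adjusted p = 1.18e-08) and Cd14 4.02-fold from 174 ± 9.65 CPM (adjusted p = 6.38e-12). Pparg, a lipid-sensing nuclear receptor, was 3.62-fold lower, from 49.1 ± 5.06 to 13.6 ± 1.35 CPM (adjusted p = 2.46e-09), and Kcnj2 9.11-fold lower (adjusted p = 5.37e-07). Slc39a10 (log2 fold change -0.17, adjusted p = 0.0994; 0.0041 with the block) and Mt2 (-0.10, adjusted p = 0.843) did not pass here, while Mt1 was 1.25-fold lower (adjusted p = 0.0134) and Slc30a1, chosen after its values were seen, fell by -0.76 ± 0.15 in log2 (adjusted p = 0.00166).

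Platelet markers were higher for 20 of 21 (21 adjusted over the list alone; camera, adjusted p = 1.48e-37, adjusted p = 0.00182 with an estimated correlation), and Ppbp rose 167-fold (adjusted p = 1.23e-07). Of 11 cAMP response genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera, adjusted p = 2.99e-10, adjusted p = 0.00182 with an estimated correlation), and of 16 TGF-beta response genes 10 rose and 0 fell (12 higher adjusted over the list alone, 12 higher and 2 lower with the block; camera, adjusted p = 1.7e-10, adjusted p = 0.0207 with an estimated correlation). Inflammatory genes gave 7 rises and 2 falls among 19 (8 and 2 adjusted over the list alone, 9 and 4 with the block; camera, adjusted p = 0.025, adjusted p = 0.472 with an estimated correlation). The interferon list held 3 rises among 21 but 0 adjusted over the list alone (3 at an unadjusted p under 0.05, 1 with the block; camera, adjusted p = 0.428). In all, edgeR called 3960 genes, 1850 higher and 2110 lower (6499, 3057 and 3442 with the block), of which 298 and 252 changed at least 2-fold. Without replicate number 1 there were 2422.

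Between activated and resting platelets, the effect of thrombin when platelets are present, platelet markers and cAMP response genes rose as lists. Trem1 rose 9.84-fold (adjusted p = 1.06e-06), Il1b 4.13-fold (adjusted p = 7.12e-05), Tgm2 5-fold (adjusted p = 1.41e-06), Vegfa 3.71-fold (adjusted p = 1.84e-07) and Cd14 2.74-fold (adjusted p = 9.55e-10). Nt5e, the ectoenzyme CD73 that makes adenosine, rose 5.44-fold from 2.18 ± 0.686 to 11.9 ± 2.23 CPM (adjusted p = 6.35e-05). Platelet transcripts also differed, Ppbp by 7.6-fold (adjusted p = 7.31e-05) and Nrgn by 7.39-fold (adjusted p = 6.2e-05). Mt2 was 5.65-fold lower (adjusted p = 2.41e-06), Slc39a10 2.58-fold higher (adjusted p = 2.5e-08) and the insulin signalling gene Irs1 3.29-fold lower (adjusted p = 0.00151). Ighm fell 3.09-fold (adjusted p = 0.00188). Several genes that rose with resting platelets did not differ here, among them Tgfbr1 (log2 fold change -0.04 ± 0.08, adjusted p = 0.808) and Gjb2 (-0.38 ± 0.26, adjusted p = 0.364).

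Platelet markers rose for 17 of 21 (21 adjusted over the list alone and with the block; camera, adjusted p = 3.14e-31, adjusted p = 0.00191 with an estimated correlation). Of 11 cAMP response genes 7 rose and 0 fell (9 adjusted over the list alone and with the block; 0 fell in either; camera, adjusted p = 3.98e-10, adjusted p = 0.00191 with an estimated correlation), with Pde4d 3.35-fold (adjusted p = 1.94e-07) and Crem 2.16-fold higher (adjusted p = 3.69e-06). Inflammatory genes gave 3 rises and 2 falls among 19 (5 and 2 adjusted over the list alone, 4 and 2 with the block; camera, adjusted p = 0.407). Of 17 genes for phagocytosis and uptake of apoptotic cells 1 rose and 5 fell (the same adjusted over the list alone, 2 and 9 with the block; camera, adjusted p = 0.0213, adjusted p = 0.0611 with an estimated correlation). Gas6, a bridging ligand for apoptotic cells, was 1.39-fold lower (adjusted p = 0.00711), Elmo1 1.22-fold lower (adjusted p = 0.000156) and the integrin gene Itgb5 1.26-fold higher (adjusted p = 0.0011). Of 22 immediate early genes 9 rose and 3 fell (11 and 4 adjusted over the list alone, 11 and 5 with the block; camera, adjusted p = 0.00432, 0.0749 with the block, and adjusted p = 0.245 with an estimated correlation). Cxcl2 (adjusted p = 0.0647) and Socs3 (adjusted p = 0.0584) did not pass, but did with the block (0.0045 and 0.00286) and by DESeq2 (0.0398 and 0.0418). Without activated platelets 1 Cxcl2 passed (0.0379), as did Socs3 without resting platelets 4 (0.0198), and Tnf (adjusted p = 0.68) without activated platelets 2 (0.0323). In all, edgeR called 2472 genes, 1146 higher and 1326 lower (5391, 2489 and 2902 with the block), of which 166 and 100 changed at least 2-fold. Without replicate number 1 or 3 there were 972 and 1375.

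The interaction tests whether adding thrombin acts differently with platelets than without them. It thus also holds the activation of the platelets and the larger share of platelet transcripts that came with it. The sharpest case was Cd14, which was lower with thrombin alone and higher when thrombin was added with platelets, an interaction of 1.75 ± 0.08 in log2 (adjusted p = 9.71e-09). Pde4d (1.85 ± 0.18, adjusted p = 2.03e-05), Tgm2 (2.34 ± 0.27, adjusted p = 0.000104), Il1b (2.56 ± 0.41, adjusted p = 0.00126) and Trem1 (3.01 ± 0.52, adjusted p = 0.00189) had positive interactions. Negative ones included Lrrc14b (-2.56 ± 0.31, adjusted p = 0.00012), Kcnj2 (-2.53 ± 0.37, adjusted p = 0.000671) and Pparg (-1.50 ± 0.13, adjusted p = 9.55e-06). Of the zinc genes, Mt2 at 0.30 ± 0.33 (adjusted p = 0.621), Mt1 at -0.09 ± 0.12 (adjusted p = 0.723) and Slc39a10 at -0.30 ± 0.11 (adjusted p = 0.0824; 0.00241 with the block) gave no call. Slc30a1, chosen after its values were seen, had a negative interaction of -0.77 ± 0.21 (adjusted p = 0.031).

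Of 11 cAMP response genes 6 had a positive and 0 a negative interaction (the same adjusted over the list alone, 9 and 0 with the block; camera, adjusted p = 3.07e-07, adjusted p = 0.00944 with an estimated correlation). For platelet markers the numbers were 6 and 0 of 21 (8 adjusted over the list alone, 11 with the block; camera, adjusted p = 3.59e-07, adjusted p = 0.267 with an estimated correlation), and for TGF-beta response genes 2 and 0 of 16, namely Ski and Tgfbi (6 adjusted over the list alone, 8 and 2 with the block; camera, adjusted p = 0.00013, adjusted p = 0.267 with an estimated correlation). Macrophage identity genes gave 2 and 0 of 17, with Cd14 among them (4 adjusted over the list alone, 6 and 3 with the block; camera, adjusted p = 0.00176, adjusted p = 0.475 with an estimated correlation). In all, edgeR called 1550 interactions, 712 positive and 838 negative, with 4535 under the block (2049 and 2486). Interactions also went with transcript GC content (Spearman rho = 0.382). Of the 1550 genes, 1260 were also called between activated and resting platelets. The interaction contains that difference, so an overlap is built in. Without replicate number 1, 3 or 4 there were 264, 755 and 1003 interactions called.

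Resting platelets against vehicle and activated platelets against thrombin share no library, so their overlap is free of shared controls. They do share the same fit and its estimate of spread per gene, so genes with little spread are called more readily in both. Values for independent lists, here and below, may therefore be too low. These comparisons had 203 genes called higher in both and 121 lower in both, where 38.3 and 27.8 would be shared by independent lists, and 14 called in opposite directions. Tgm2, Ptgs2, Vegfa and Map2k6 were among the 324 shared calls. Log2 fold changes correlated across all genes at r = 0.653, and at r = 0.55 without the platelet and erythroid lists, which left 311 shared calls. That removal left 15586 of 15610 genes, so other RNA carried with the platelets may remain among them. With the block 869 higher and 881 lower calls, 1750 in all, were shared (334 and 365 for independent lists), and 335 were opposite. The 324 fell to 183, 179 and 211 without vehicle 1, 2 and 4, to 171, 178 and 193 without resting platelets 1, 2 and 4, and to 56, 131 and 98 without replicate number 1, 2 and 4. Against the shared vehicle libraries, resting and activated platelets had 266 higher and 156 lower calls in common (39.5 and 28 for independent lists). Their covariance was 0.115, compared with 0.0208 in 10 simulations of unchanged groups, where 0 calls were shared. The correlation was 0.768 (0.478 simulated, and 0.367 to 0.563 with the controls split).

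Thrombin against vehicle and activated against resting platelets shared 5 higher calls and 12 lower calls (1.03 and 2.63 for independent lists), with 6 in opposite directions and r = 0.0816 across genes. The 17 in the same direction are out of 45 calls of thrombin against vehicle. Both sets of log2 fold changes went with transcript GC content, in opposite directions (Spearman rho = -0.443 and 0.205), which bears on r and on the opposite calls. The same-direction calls included Slc39a10, Mt1, Mt2, Zfp143 and Klhl17. With the block, 107 and 158 were shared (97.3 and 125 for independent lists), 265 in all. More calls, 393, were opposite, and no value for independent lists was computed for these.

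**Figure D4:**
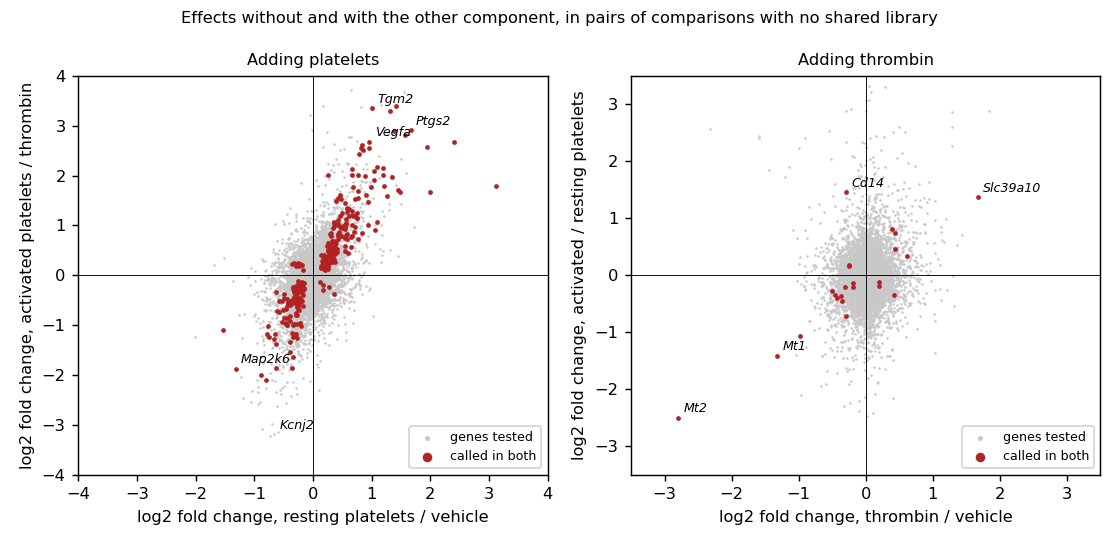
Log2 fold changes of the tested genes that lie within the axes, in pairs of comparisons with no shared library: platelets without and with thrombin (left), and thrombin without and with platelets (right). Red points were called in both; r = 0.653 for platelets and 0.0816 for thrombin, with Mt1, Mt2 and Slc39a10 the farthest from 0 among genes called in both.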

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

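Tests of platelet RNA carried into the libraries, of induction of platelet genes by the macrophages and of the amount of platelet RNA were chosen after the results they concern were seen.

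In each group of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was divided by the whole range, for 428 groups of values. Of these 25, or 5.84%, stood out as far from the others, where chance gives about 5%, so the set as a whole holds no clear excess. They fell in replicates 1 to 4 in numbers of 2, 11, 5 and 7. The causes were not tested.

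In vehicle, low counts gave a ratio of 1 for Nrgn (replicate 4, 0.0714 CPM), Cd226 (replicate 3, 0.0366 CPM), Hba-a1 and Hba-a2 (replicate 4, 0.0357 CPM each) and Alox12 (replicate 3, 0.0732 CPM), each at 0 in the other libraries. Other vehicle values that stood out were Fos (0.894, replicate 1, 49.8 against 55.7 to 56.4 CPM), Vegfa (0.9, replicate 2, 30.2 against 41.9 to 43.2 CPM), Hk2 (0.867, replicate 4, 48.6 against 52.5 to 53.1 CPM) and Crem (0.866, replicate 3, 12.2 against 8.91 to 9.35 CPM). So did Plaur (0.86, replicate 2, 46.6 against 35.9 to 37.4 CPM), Pparg (0.851, replicate 2, 54.8 against 42.7 to 44.5 CPM) and the total (0.922, replicate 2, 22.6 against 27.3 to 27.7 M counts).

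With thrombin these were Has2 (0.915, replicate 4, 4.72 against 2.73 to 2.9 CPM), Lpl (0.853, replicate 2, 4090 against 2390 to 2640 CPM), Osgin1 (0.833, replicate 3, 16.5 against 15.3 to 15.5 CPM) and Clec4e (0.844, replicate 2, 13.9 against 16.6 to 17.1 CPM). With resting platelets they were Slc19a2 (0.917, replicate 3, 16.7 against 18.9 to 19.1 CPM), Klf2 (0.87, replicate 4, 8.19 against 5.49 to 5.84 CPM), Lpl (0.863, replicate 2, 3480 against 2090 to 2280 CPM) and Clec4e (0.894, replicate 2, 24.5 against 19.8 to 20.3 CPM). With activated platelets they were Il1rn (0.843, replicate 4, 56.5 against 66.2 to 68 CPM), Tnf (0.896, replicate 2, 22.2 against 9.36 to 10.7 CPM) and Pf4 (0.905, replicate 1, 279 against 237 to 241 CPM). Gng11 (0.927, replicate 2, 48.8 against 37.9 to 38.7 CPM) and Clec4e (0.836, replicate 2, 55.5 against 42.7 to 44.8 CPM) stood out there too.

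The effect of adding thrombin differed with platelets present for 1550 genes by the interaction test of edgeR. That difference also holds the activation of the platelets and the larger share of platelet transcripts. Among the 23 genes called in both thrombin comparisons, 6 went in opposite directions. Among them, interaction log2 fold changes were -0.32 for Stam2, 0.41 for Med25, -0.38 for Ptgr2, -0.76 for Ccdc122 and 1.75 for Cd14, with adjusted p = 0.00129, 0.00156, 0.000527, 0.00104 and 9.71e-09.

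Whether chance gives as many calls was tested by refitting every other split of the 8 libraries in a comparison. For each of the 5 pairs of groups 1 of 35 splits, the real one, gave as many calls. The real counts were 45, 529, 4031, 3960 and 2472, and the highest of the other splits was 0, except 1 for resting platelets against vehicle. Splits that mix groups that differ put this difference into the spread within groups, which lowers the calls. Their low counts therefore do not show how many calls chance alone gives. The rank of the real split, 1 of 35, is a share under 0.05 only if libraries are exchanged freely. Since replicate numbers pair the libraries, the like splits are the 8 that part all 4 pairs, the real one included, and 8 are too few for a share under 0.05. For the interaction 1 of 100 draws, the real one, gave as many as 1550. The highest other draw gave 913, and was 1 of 3 that keep activated and resting libraries apart. The other draws mix these libraries and gave 0, which the design brings about, so the draws do not settle whether chance gives as many interactions.

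Platelet and megakaryocyte transcripts rose in both platelet groups. Induction of platelet genes by the macrophages alone would leave haemoglobin transcripts at the level of the platelet-free libraries. They were above every such library in 8 of 8 platelet libraries (0.712 to 2.98 CPM with resting and 7.48 to 14.1 CPM with activated platelets, against at most 0.0714). This goes with carried RNA of blood cells. It cannot decide where the platelet transcripts came from, since haemoglobin genes are not platelet genes and were already called higher. If RNA of blood cells were carried into the libraries, platelet and haemoglobin genes would rise in similar proportion between the platelet groups. The ratio of their medians was 1.22. The platelet genes used were those called with resting platelets, with ratios from 4.89 (Cd226) to 10.8 (Gp6). Hba-a1 and Hba-a2 had 5.42 and 5.6. Markers not called with resting platelets were left out, so the similar proportion holds for the genes used alone. Carried platelet RNA thus stays a candidate explanation, as a hypothesis. Induction of platelet genes by the macrophages stays open beside it.

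The response to activated platelets was larger than that to resting platelets. If the amount of platelet material carried over set the size of the macrophage response, the slope of the resting on the activated response over genes outside the platelet lists would lie within the ratios of platelet transcripts. The slope over 3937 called genes was 0.344 (0.313 to 0.373 over 1000 resamples of those genes). These genes were picked by their calls, which can shift the slope, and the resamples leave out the spread between libraries. The ratios of 9 platelet transcripts ran from -0.0855 to 0.443 with a median of 0.149. The slope lies within that range only because of Itgb3 at 0.443, since the 6 transcripts called with resting platelets had ratios of 0.125 to 0.165. The slope is also on the log2 scale while the ratios are of CPM, and the median CPM ratio per gene was 0.216. The test therefore does not decide, and the amount of platelet material stays open beside activation by thrombin, which the design names.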

How the results depend on the processing

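The replicate block with GC correction, the omission of whole replicate numbers, the fits without the platelet lists, and the overlap with a block or without libraries were chosen after the data were seen. Of 387 values for genes named by the rule, 345 were calls. Among values called in the main fit or in the alternative, 0 changed direction in edgeR, limma-voom or DESeq2. DESeq2 could be compared for 364 values. Signs of values called in neither fit were not compared. A stricter filter changed 0 of 368 and fits without the platelet lists 0 of 329. Calls ended for 1 gene value with RLE factors, 4 with upper quartile factors, 10 with limma-voom, 32 with no filter, 27 of 318 in fits of 2 groups, 1 with the block and 4 with the block and GC correction. Calls were gained for 8, 8, 4 and 1 with the block, the block and GC correction, DESeq2 and limma-voom. Omitting 1 library ended a call in 296 of 3576 fits, for 54 values. Values of genes named outside the rule were refitted with the block, and some, such as Slc30a1 for thrombin against vehicle, also with the block and GC correction. Of 168 list results 52 passed, 18 of them with an estimated correlation. Of those that also passed with fry, the block or RLE factors, 0 changed direction. Directions were not compared for the estimated correlation. The block ended 11 and added 19, and fry ended 7 and added 12. In the order thrombin, resting platelets and activated platelets against vehicle, activated platelets against thrombin and against resting platelets, and interaction, the block gave 1285, 3360, 6635, 6499, 5391 and 4535 calls, and with GC correction 407, 2699, 6888, 6692, 5328 and 3579. A minimum of 2-fold left 3, 39, 598, 550, 266 and 139. For thrombin and for resting platelets against vehicle, DESeq2 gave 160 and 953, and fits of 2 groups 11 and 188. With no filter resting platelets gave 335. The ranges without replicates were 4 to 27, 58 to 550, 2522 to 3727, 2422 to 3798, 972 to 2256 and 264 to 1672. The overlap of 324 calls was 500 with DESeq2, 1750 with the block, 1857 with GC correction too, 105 at an adjusted p under 0.01, 37 at 2-fold, and 56 to 349 without replicates. The platelet share of activated platelets minus thrombin was 0.0221 to 0.024 without replicates (0.0232 with all; exact p = 0.0571, the smallest for 3 against 4). The 2-fold minimum and smaller groups lower counts by construction, and for the other changes the cause was not tested. Totals of 22.6 to 30.6 M counts and 4 libraries limit small changes, since 74.6% of simulated 1.5-fold changes were recovered.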

Other observations

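The correction for GC content was added, and Slc30a1 and the mitochondrial ribosomal RNAs were chosen, after the data were seen.

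Other gene groups moved in part with activated platelets against vehicle. Of 17 NRF2 and oxidative stress genes 5 rose and 2 fell by edgeR (6 and 3 adjusted over the list alone, 8 and 4 with the block), led by the cystine importer gene Slc7a11, 3.55-fold higher (adjusted p = 1.09e-05), with camera at adjusted p = 0.226 (0.0225 with the block, and 0.233 with the block and an estimated correlation). Among 14 antigen presentation genes Cd86, a costimulatory ligand, rose 2.24-fold (adjusted p = 0.000105) and Cd80 1.66-fold (adjusted p = 0.00356), while Ciita, which drives MHC class II genes, was 2.52-fold lower (adjusted p = 0.00443). Of 20 cell cycle genes 2 rose and 2 fell (6 and 3 with the block), among them Ccnd1, 2.05-fold lower (adjusted p = 0.00121). Of 16 unfolded protein response genes 3 fell, among them Herpud1, 1.45-fold lower (adjusted p = 0.00176). Of 10 heat shock genes 2 rose and 1 fell, with Hsph1 1.65-fold higher (adjusted p = 8.23e-07). Of 20 sterol genes 3 rose and 1 fell (1 and 1 adjusted over the list alone). In none of these lists did camera pass without the block.

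The ribosomal RNAs of the mitochondrial genome, chosen after their values were seen, rose with both kinds of platelets. Against vehicle, with activated platelets mt-Rnr2 went from 277 ± 41.1 to 1180 ± 200 CPM (SD, n = 4), 4.26-fold (adjusted p = 1.84e-07 by edgeR), and mt-Rnr1 from 103 ± 16.5 to 541 ± 98.8 CPM, 5.25-fold (adjusted p = 1.16e-07). With resting platelets mt-Rnr2 rose 1.6-fold (adjusted p = 0.0318) and mt-Rnr1 1.59-fold (adjusted p = 0.0478). The interactions were 1.08 ± 0.23 for mt-Rnr2 and 1.46 ± 0.25 for mt-Rnr1 in log2 (SE; adjusted p = 0.00721 and 0.00173). The cause was not tested. The protein genes of that genome were not analysed here.

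The log2 fold changes of thrombin against vehicle went with transcript GC content, with a Spearman rho of -0.443 before and 0.0239 after correction. Of the 1285 calls made with the replicate block, 24.6% passed after the correction, which took the median absolute log2 fold change of those calls from 0.175 to 0.114 and their median SE from 0.042 to 0.038. Of these calls 98.8% kept their sign. Of the 45 calls made without the block, 38 passed after the correction. A GC difference between libraries is thus a candidate explanation for many small changes. Of the calls with the block, 53.8% had the same sign between activated and resting platelets after correction of that comparison (41.9% without it). That comparison also holds the activation of the platelets, so an effect of thrombin that occurs with platelets too stays open. For the zinc genes a GC difference between libraries as the whole cause is argued against, since 4 of the 4 genes Mt1, Mt2, Slc30a1 and Slc39a10 passed after correction, and a response to thrombin or to what came with it stays open as a hypothesis.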
